A study of Mus musculus with 6 samples.

How the data were processed

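Total RNA was isolated from common myeloid progenitors (CMP) of C57BL6 mouse bone marrow that had been sorted by H2-DCFDA fluorescence into fractions of low and high content of reactive oxygen species, per the labels' protocols. The RNA was amplified and labelled with biotin by the NuGEN Ovation system, per the labels' protocols, and read on one-colour Affymetrix-type mouse arrays. The deposited values are one linear intensity per probe set and array. How the authors summarised probes into these intensity values and scaled the arrays is not given in the sources used here. The values are never below 0.8. The array medians, 40.4 to 42.5, and trimmed means (2% of each tail trimmed), 181 to 198, are similar but not equal, so the arrays are on a roughly comparable scale. The medians lie near background and say little about bright probe sets, and the trimmed mean was lowest, at 181, on high-ROS replicate 3. Small shifts can therefore depend on the scaling. The values carry no detection call, so no probe set was called present or absent, and signals near the median are read as near background. Only the 6 array columns hold values, and each was matched to its sample through the labels.

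Probe sets were named from a table of the platform's annotation. Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed and are unnamed here. The Entrez Gene identifier of 34741 named probe sets was found in the RefSeq gene table (assembly GRCm38.p6), and 0 symbols changed. The genome build behind the probe sets is not given in the sources used here, so no coordinates are printed. Probe sets with several symbols or none were left out of the gene-level comparison. Of the 18193 genes, 9010 had more than 1 probe set, and the one with the highest mean over the 6 arrays stood for the gene. Members of gene lists with no probe set of a single name are not analysed here.

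A pseudocount of 16 was added before taking log2, and the arrays were not normalized further, because their medians on this scale lay within 0.1. High-ROS was compared with low-ROS CMP, 3 arrays against 3, with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 4 residual degrees of freedom, 11.1 with those borrowed across genes. Fold changes are on the scale of the signal plus pseudocount, which shrinks those of dim genes. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none is given for single genes. Mean ± SD values are deposited signals with n = 3 arrays per group.

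For 21 gene lists (lineages, other cells of the marrow, antioxidant and metabolic pathways, cell cycle, stress and the gate's surface proteins), camera of limma compared the members with all other genes at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists. Each list was tested again with its own estimated correlation and with fry. Within each list, members were also adjusted over the list alone. Of all possible list pairs, 16 shared 1 to 3 genes, such as Csf1r, Gata2 and Slamf1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

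The genes named in the text were set by rule: those past the threshold with groups that did not overlap, up to 8 in each direction, the 2 members of each list with the smallest unadjusted p (4 for the erythroid, megakaryocyte, granulocyte-monocyte, stem and multipotent progenitor and peroxide and superoxide removal lists), and Kit, Cd34, Fcgr3, Fcgr2b, Ly6a, Gata1, Klf1, Cebpa, Spi1 and Mpo whatever their p; 1 further gene of the rule is not analysed here. Others named, among them the members that passed adjusted over a list alone, Ppbp, Tubb1, S100a8 and S100a9, were chosen after their values were seen. The groups, the tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except 3 alternatives that were added later.

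The alternatives fixed beforehand were a fit with no mean-variance trend, only genes above the median signal, quantile normalization, the mean of a gene's probe sets, the replicate number as a block, array weights, pseudocounts of 1 and 64, leaving out each array in turn, one test per probe set, an adjusted p under 0.1, a minimum 2-fold change, an estimated correlation and fry. Added after seeing the data were leaving out both arrays at the ends of the first principal component, the log2 Gapdh 3' to 5' ratio as a covariate, and lists reduced to members on no other list.

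The steps were tested on simulated data made from the real genes' means and spreads, with 200 of 18193 genes changed in each of 20 simulations. Of genes changed by a log2 size of 1, 57.7% were called in the right direction, and 94.55% of those changed by a log2 size of 2. Of the calls, 3.73% were false. The megakaryocyte list, shifted by a log2 size of 0.3, was called in 20 of 20 simulations, with 0 calls among 340 tests of unshifted lists. Genes were simulated as independent, so this says nothing about lists whose members vary together.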

Results

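Common myeloid progenitors (CMP) are bone marrow cells that give rise to granulocyte-monocyte progenitors and to megakaryocyte-erythrocyte progenitors. Bone marrow cells of C57BL6 mice were stained with H2-DCFDA, a dye that fluoresces when reactive oxygen species (ROS) oxidise it, and CMP from the low and the high end of this staining were sorted by flow cytometry. Gene expression was measured on 6 one-colour arrays, 3 of low-ROS CMP and 3 of high-ROS CMP, each with 45101 probe sets. The series addresses the part that ROS play in the passage of CMP to megakaryocyte-erythrocyte progenitors. The labels do not say whether the 3 samples of a group came from separate mice or separate sorts. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The camera p-values set list members against all other genes, so at the preset correlation they mainly measure the spread between genes. For the stem and multipotent progenitor list the unadjusted camera p was 2.57e-14, against 0.00258 with an estimated correlation and 0.00155 with fry. The number of arrays limits the precision of every value.

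The arrays resembled each other closely. Median signals lay between 40.4 and 42.5. Over all genes the correlation between arrays ranged from 0.975 to 0.991, with a mean of 0.986 within groups and 0.984 between them. The first principal component carried 33.2% of the variance, with the low-ROS arrays between -25.8 and -7.14 and the high-ROS arrays between -0.252 and 36.6. Low-ROS replicate 1 and high-ROS replicate 3 were at its ends. The ratio of 3' to 5' signal of control probe sets is a measure of RNA integrity and of labelling. For Gapdh it was 3.19, 2.84 and 2.54 in low-ROS replicates 1 to 3 and 3.57, 2.997 and 4.53 in high-ROS replicates 1 to 3. For Actb it lay between 0.976, in low-ROS replicate 1, and 1.06, in high-ROS replicate 3. Xist signals between 2134 and 4519 and Eif2s3y signals between 9.03 and 15.2 on the 6 arrays showed no array that differed in the sex of its cells.

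Few single genes separated the groups. Of 18193 genes, 7 fell and 3 rose in high-ROS CMP at an adjusted p under 0.05 (limma), and all 10 had groups that did not overlap. Ctla2a, which encodes an inhibitor of cathepsin-type proteases, showed the smallest p: its signal was 3670 ± 23.7 (SD, n = 3) in low-ROS CMP and 1541 ± 93.9 (SD, n = 3) in high-ROS CMP, 2.37-fold lower (log2 fold change -1.25, SE 0.0872, adjusted p = 0.000324). Its near-identical paralog Ctla2b fell from 1491 ± 79.0 to 526 ± 104 (log2 fold change -1.49, SE 0.144, adjusted p = 0.00455), and probe sets of such close copies may read each other's transcripts. F2r, a thrombin receptor, fell 3.44-fold, from 1156 ± 98.9 to 335 ± 116 (log2 fold change -1.78, SE 0.199, adjusted p = 0.00927). Angpt1, the ligand of the receptor tyrosine kinase Tek, fell 2.15-fold, from 935 ± 22.0 to 426 ± 12.1 (log2 fold change -1.11, SE 0.117, adjusted p = 0.00729).

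The other 3 genes that fell were Cavin2, a coat protein of caveolae, with a log2 fold change of -1.17 (SE 0.161) on the chosen probe set and -0.70 and -0.02 on its other ones, both dim, Tgfbr3, a co-receptor for transforming growth factor beta, with -1.11 (SE 0.155), and Rgs1, which dampens G protein signalling, with -0.73 (SE 0.104). Each had an adjusted p of 0.0445. The genes that rose were Cnn3, an actin-binding calponin, with a log2 fold change of 1.10 (SE 0.160, adjusted p = 0.0490), Amot, an angiomotin that acts in Hippo signalling, with 1.01 (SE 0.145, adjusted p = 0.0445), and Chdh, the mitochondrial choline dehydrogenase, with 0.90 (SE 0.125, adjusted p = 0.0445). Cnn3 signal was 222 ± 33.9 (SD, n = 3) in low-ROS and 492 ± 43.04 in high-ROS CMP. For Amot, the chosen probe set was the brightest of 3, and the other two had log2 fold changes of -0.16 and 0.21. The Entrez Gene identifiers are 13024 for Ctla2a, 13025 for Ctla2b, 14062 for F2r, 11600 for Angpt1, 20324 for Cavin2, 21814 for Tgfbr3, 50778 for Rgs1, 71994 for Cnn3, 27494 for Amot and 218865 for Chdh.

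An unadjusted p under 0.05 was reached by 808 genes in the upward and 613 in the downward direction, and 2429 genes, 13.4%, had groups that did not overlap, where chance gives 10%. All 10 genes kept their sign in 16 alternative settings, but the calls did not: without a mean-variance trend limma called 0 genes (829 higher and 522 lower at an unadjusted p under 0.05). Leaving out any 1 of the 6 arrays left 0 genes higher, and 6 lower without high-ROS replicate 3, 2 without high-ROS replicate 2 and 1 without each of the others.

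**Figure D1:**
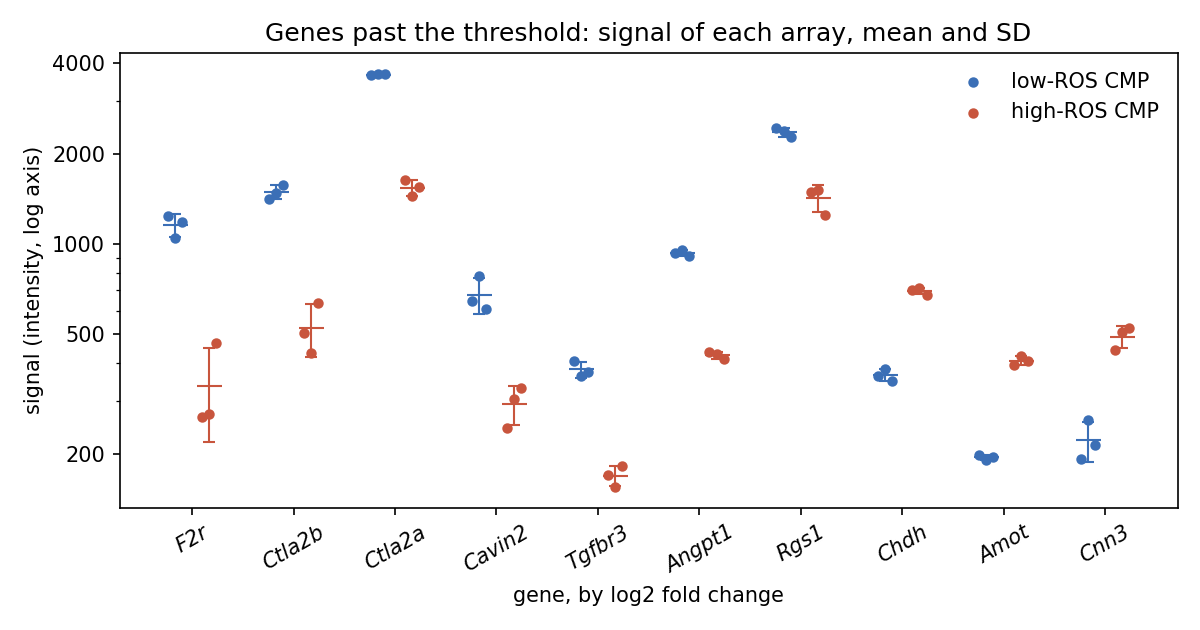
Signal (intensity, log axis) of the 10 genes past the threshold on each of the 6 arrays, with the mean and SD of the 3 low-ROS (blue) and 3 high-ROS (red) arrays of each gene. The 3 high-ROS arrays lie below all low-ROS arrays for the 7 genes from F2r to Rgs1 and above them for Chdh, Amot and Cnn3.

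Genes of stem cells and multipotent progenitors fell as a group in high-ROS CMP. Of 27 measured members, 24 had a lower mean in high-ROS CMP and 3 a higher one, with a median log2 fold change of -0.36 (camera adjusted p = 5.39e-13; adjusted p = 0.0271 with an estimated correlation). Over all genes 1 member passed, Angpt1. Adjusted over the list alone, 6 were lower, 0 were higher and 21 did not pass. The 6 were Angpt1, Tek, Slamf1, Fgd5, Hlf and Hoxa10. Tek, the receptor for Angpt1, had 262 ± 117 (SD, n = 3) in low-ROS and 49.0 ± 22.4 in high-ROS CMP, a log2 fold change of -2.07 (SE 0.326, adjusted p = 0.0643 over all genes). Slamf1, the stem cell surface protein CD150, had a log2 fold change of -1.18 (SE 0.268), and Fgd5, a marker of stem cells, -0.86 (SE 0.228), both from signals near background. On each of the 3 low-ROS arrays the mean of the list was above that on every high-ROS array.

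Megakaryocyte genes fell as well. Of 26 measured members, 23 were lower and 3 higher in high-ROS CMP, with a median log2 fold change of -0.26 (camera adjusted p = 5.14e-11; adjusted p = 0.0271 with an estimated correlation). F2r passed over all genes. Adjusted over the list alone, 7 were lower, 0 were higher and 19 did not pass. Besides F2r these were Pf4, Rab27b, Slc18a2, Gata2, Fli1 and Itga2b, the last from signals near background. Pf4, a chemokine stored in platelet granules, had 1107 ± 41.6 (SD, n = 3) in low-ROS and 666 ± 116 in high-ROS CMP, a log2 fold change of -0.73 (SE 0.141). Rab27b, a small GTPase of platelet granules, had a log2 fold change of -1.25 (SE 0.260), and Slc18a2, a monoamine transporter, -0.74 (SE 0.152). The signal of Rab27b was 108 in low-ROS and 38.3, near background, in high-ROS CMP. Gata2, a transcription factor of stem cells and early megakaryocytes, had -0.72 (SE 0.157) on the chosen probe set and -1.48 (SE 0.160) on its other one, which passed when each probe set was tested alone (adjusted p = 0.0147). The platelet transcripts Ppbp, at 23.2 and 33.7 in low- and high-ROS CMP, and Tubb1, at 14.4 and 21.2, stayed near background in both groups.

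Erythroid genes were lower by a smaller amount. Of 32 measured members, 24 were lower and 8 higher in high-ROS CMP, with a median log2 fold change of -0.09 (camera adjusted p = 0.000252; adjusted p = 0.0675 with an estimated correlation). None passed over all genes or adjusted over the list alone (0 of 32), and 4 were lower at an unadjusted p under 0.05. These were Mfsd2b, with a log2 fold change of -0.62 (SE 0.153), Slc14a1, a urea transporter, with -0.60 (SE 0.159), Slc4a1, the band 3 anion exchanger, with -0.30 (SE 0.0877), and Car2, a carbonic anhydrase, with -0.21 (SE 0.0915). The erythroid regulators Gata1 (log2 fold change -0.32, SE 0.207) and Klf1 (-0.04, SE 0.154) did not differ by more than the spread between arrays. Without high-ROS replicate 2 the list's median was -0.06 (adjusted p = 0.00764), and without both arrays at the ends of the first component -0.14 (adjusted p = 1.83e-07).

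**Figure D2:**
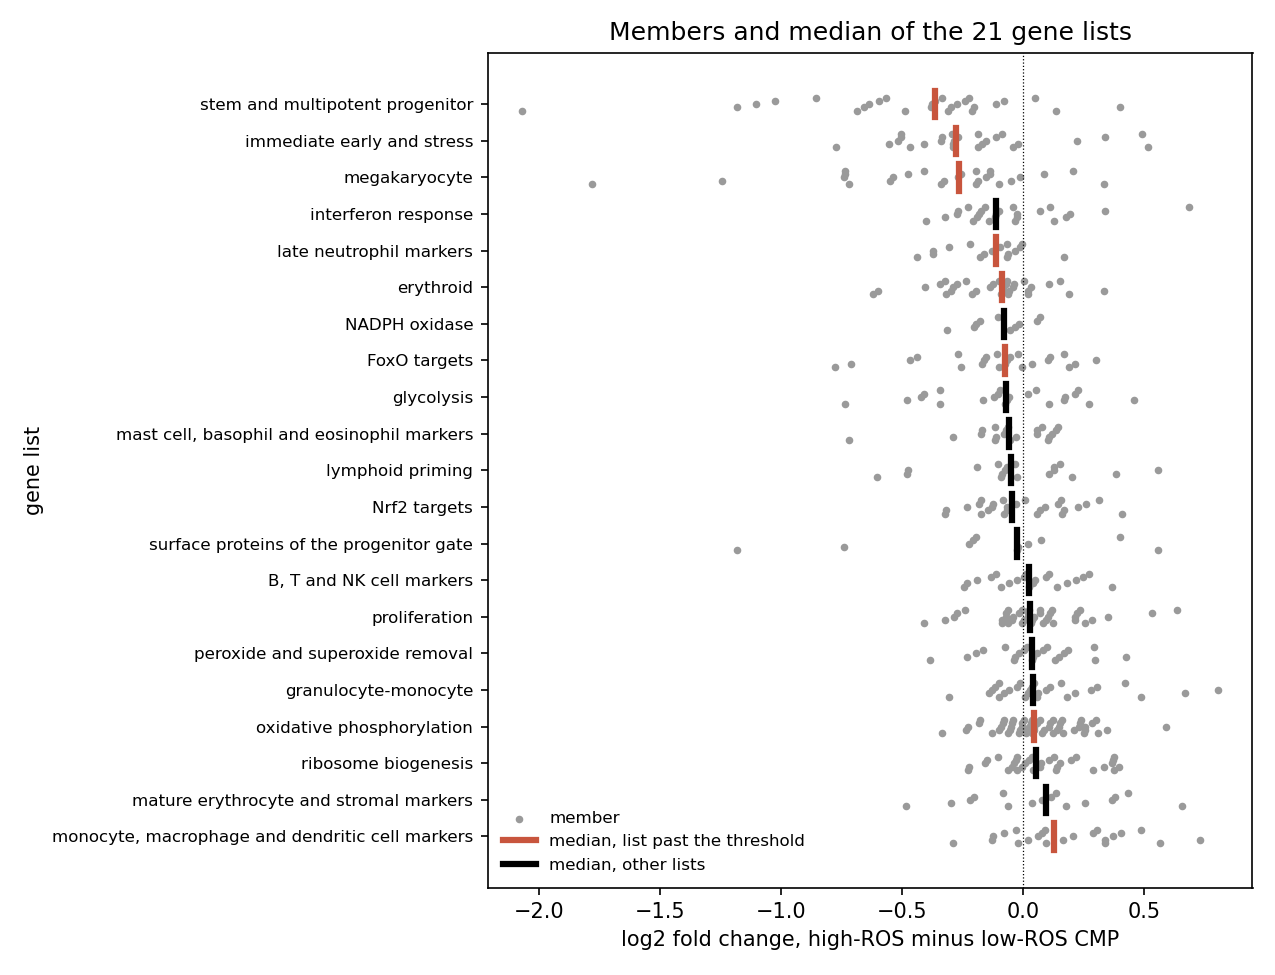
Log2 fold change between high-ROS and low-ROS CMP (horizontal axis) of each measured member (grey points) and the median (bars) of the 21 gene lists, ordered by median, with the 8 lists past the threshold in red. The medians run from -0.36 for stem and multipotent progenitor genes to 0.13 for monocyte, macrophage and dendritic cell markers.

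Genes of the monocyte side of the myeloid branch lay higher in high-ROS CMP. The list of monocyte, macrophage and dendritic cell markers had 16 of 22 measured members higher and a median log2 fold change of 0.13 (camera adjusted p = 0.00471; adjusted p = 0.326 with an estimated correlation). None passed over all genes (0 of 22). Adjusted over the list alone, 3 were higher, 0 were lower and 19 did not pass. The 3 were Ms4a6c, with a log2 fold change of 0.73 (SE 0.139) on the chosen probe set and 0.04 (SE 0.197) on its other one, Csf1r, the receptor for macrophage colony-stimulating factor, with 0.49 (SE 0.136), and F13a1, with 0.34 (SE 0.101). Without low-ROS replicate 3 this list's median was 0.03 (adjusted p = 0.0591), and with the Gapdh ratio as a covariate, a setting chosen after the data were seen, it was 0.02 (adjusted p = 0.165).

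The granulocyte-monocyte list did not pass, with 18 of 28 measured members higher and a median log2 fold change of 0.04 (camera adjusted p = 0.0541). Adjusted over the list alone, 3 of its members were higher, 0 were lower and 25 did not pass, against 0 over all genes. These were Ly86 (log2 fold change 0.81, SE 0.151), Irf8, a transcription factor of monocyte and dendritic cell development (0.67, SE 0.172), and Csf1r. The other probe set of Irf8, of similar brightness, had 0.25 (SE 0.231). Cst7 had a log2 fold change of 0.42 (SE 0.136). The granulocytic gene Mpo, at 6822 ± 268 (SD, n = 3) and 7103 ± 400, and the regulators Cebpa (log2 fold change 0.03, SE 0.164) and Spi1 (-0.01, SE 0.139) did not differ by more than the spread between arrays. Without high-ROS replicate 3, the array with the highest Gapdh ratio, the list's adjusted p was 0.00161, and it was also past the threshold with quantile normalization, at 0.00369.

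The surface proteins that define progenitor gates gave no shift as a list (11 measured, median log2 fold change -0.02, camera adjusted p = 0.120). Adjusted over the list alone, Slamf1 and Itga2b, the megakaryocyte integrin CD41, were lower and 9 did not pass. Both had signals near background, Slamf1 at 45.9 and 9.92 and Itga2b at 64.7 and 31.9 in low- and high-ROS CMP. Kit (log2 fold change -0.22, SE 0.139), Cd34 (0.40, SE 0.258), Fcgr3 (0.02, SE 0.0904) and Fcgr2b (-0.02, SE 0.120) differed by less than the test could separate from the spread between arrays. Ly6a has no probe set with a single gene name in the table used and is not analysed here.

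Genes that handle ROS did not pass as lists. Of 22 measured genes of peroxide and superoxide removal, 14 were higher and 8 lower, with a median log2 fold change of 0.04 (camera adjusted p = 0.934), and none passed adjusted over the list alone or over all genes (0 of 22). The members with the smallest p were glutathione reductase, Gsr (log2 fold change -0.23, SE 0.0959), Gpx7 (0.42, SE 0.191, from signals near background), Prdx2 (-0.19, SE 0.0891) and Txnrd2 (-0.38, SE 0.202). Targets of the oxidant-sensing factor Nrf2 had a median of -0.05 over 26 measured genes (camera adjusted p = 0.536), with Sqstm1 at -0.32 (SE 0.118). The Nrf2 median changed sign without high-ROS replicate 1 (0.07) and without low-ROS replicate 3 (0.03). It was -0.08 without both arrays at the ends of the first component, where the list passed (adjusted p = 0.0231). The NADPH oxidase list had a median of -0.08, with 8 of 10 members lower (camera adjusted p = 0.0541), and Rac1 at -0.20 (SE 0.0908) and Ncf1 at -0.32 (SE 0.174). None of the Nrf2 or NADPH oxidase genes passed over all genes or adjusted over the list alone (0 of 26 and 0 of 10). Without high-ROS replicate 1 the NADPH oxidase list passed, at 0.0396 (median -0.10). Its median was -0.13 without high-ROS replicate 2 (adjusted p = 0.0662) and -0.03 with the Gapdh ratio as a covariate (adjusted p = 0.529).

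Among the metabolic lists, genes of oxidative phosphorylation were higher by a small amount, with 34 of 53 members higher and a median log2 fold change of 0.05 (camera adjusted p = 0.0478; adjusted p = 0.515 with an estimated correlation). Ndufs7 had a log2 fold change of 0.59 (SE 0.144) and Cox5a 0.35 (SE 0.110). The call was lost without low-ROS replicate 1 (0.263), high-ROS replicate 1 (0.0928, median 0.08) or high-ROS replicate 2 (0.551, median 0.02), and the median was 0.08 without low-ROS replicate 2 and 0.09 without high-ROS replicate 3. It was 0.10 with quantile normalization (adjusted p = 0.000710) and 0.14 with the Gapdh ratio as a covariate (adjusted p = 4.70e-07). Targets of FoxO transcription factors, which respond to oxidative and growth factor signals, were lower, with 16 of 23 members lower and a median of -0.07 (camera adjusted p = 0.0373; adjusted p = 0.326 with an estimated correlation). Fbxo32 had -0.78 (SE 0.253, from signals near background) and the cell cycle inhibitor Cdkn1a -0.71 (SE 0.253). The list's call was lost without low-ROS replicate 1 (0.105, median -0.01), low-ROS replicate 2 (0.0823) or high-ROS replicate 2 (0.228, median -0.04). Its median was -0.14 without low-ROS replicate 3, -0.12 without both arrays at the ends of the first component (adjusted p = 0.0207) and -0.13 with the Gapdh covariate (adjusted p = 0.00102). Glycolysis genes had a median of -0.07 over 22 measured genes (camera adjusted p = 0.120), with Hk1 at -0.73 (SE 0.261) and Pfkp at -0.42 (SE 0.143). That list passed without high-ROS replicate 2 (0.0433, median -0.12). Its median changed sign without high-ROS replicate 3 (0.04, adjusted p = 0.532) and with the Gapdh covariate (0.06, adjusted p = 0.720). No member of these 3 lists passed over all genes or adjusted over the list alone (0 of 53, 0 of 23 and 0 of 22).

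Proliferation genes had a median log2 fold change of 0.03 over 40 measured members (camera adjusted p = 0.510), with Bub1, a mitotic checkpoint kinase, at 0.53 (SE 0.149) and E2f2 at -0.41 (SE 0.124). Ribosome biogenesis genes had a median of 0.06 over 32 (camera adjusted p = 0.120), with Dkc1 at 0.40 (SE 0.134) and Ddx18 at 0.38 (SE 0.131). Without high-ROS replicate 3 both lists were higher in high-ROS CMP, with adjusted p of 0.00249 and 0.000441. Without high-ROS replicate 2 their medians were -0.01 and 0.02, with adjusted p of 0.644 and 0.794. Interferon response genes had a median of -0.11 over 25 (camera adjusted p = 0.120), with Gbp3 at 0.69 (SE 0.175) and Rsad2 at -0.21 (SE 0.1001). Without low-ROS replicate 3 that list was lower, at 0.0208 (median -0.18), and without low-ROS replicate 1 its median was -0.02 (adjusted p = 0.299). Lymphoid priming genes had a median of -0.05 over 18 (camera adjusted p = 0.440), with Bcl11a at -0.60 (SE 0.209) and Lsp1 at -0.47 (SE 0.151). None of these members passed over all genes or adjusted over the list alone (0 of 40, 0 of 32, 0 of 25 and 0 of 18).

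Immediate early and stress genes, which respond within minutes to handling and signals, were lower in high-ROS CMP. Of 26 measured members, 22 were lower and 4 higher, with a median log2 fold change of -0.28 (camera adjusted p = 1.16e-06; adjusted p = 0.326 with an estimated correlation). None passed over all genes (0 of 26). Adjusted over the list alone, 2 were lower, 0 were higher and 24 did not pass: Nr4a1, an orphan nuclear receptor, with 1264 ± 209 (SD, n = 3) in low-ROS and 732 ± 114 in high-ROS CMP, and Ddit4, a stress-induced inhibitor of mTOR signalling, with 1804 ± 154 and 1256 ± 131. The list's mean, centred on the 6 arrays, spread widely within groups, from -0.03 to 0.30 in low-ROS and from -0.20 to 0.04 in high-ROS CMP. Its median was -0.17 without low-ROS replicate 2 (adjusted p = 0.00988), -0.15 without high-ROS replicate 3 (adjusted p = 7.73e-06) and -0.05 with the Gapdh ratio as a covariate (adjusted p = 0.0461), a setting added after the data were seen.

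Markers of other blood cells were read as a check of the sort. Late neutrophil markers were among the brightest genes of all arrays, with 9 of 16 measured members above the 95th percentile of genes on every array, S100a8 at 12746 ± 494 (SD, n = 3) and 12643 ± 225 and S100a9 at 12944 ± 302 and 12894 ± 222. They were lower in high-ROS CMP by a median log2 fold change of -0.11, with 15 of 16 lower (camera adjusted p = 0.00111; adjusted p = 0.326 with an estimated correlation), led by Cd177 at -0.44 (SE 0.161) and Cxcr2 at -0.37 (SE 0.188). The call was lost, at 0.376 with a median of -0.03, with the Gapdh ratio as a covariate, which was chosen after the data were seen. Mast cell, basophil and eosinophil markers had a median of -0.06 over 20 measured genes (camera adjusted p = 0.135), with Gata2 lower adjusted over the list alone (1 lower, 0 higher and 19 not passed) and Prg3 at -0.29 (SE 0.177). B, T and NK cell markers had a median of 0.02 and a mean of 0.03 over 21 measured genes, opposite in sign to the test (camera adjusted p = 0.934), with Blnk at 0.37 (SE 0.294) and Cd3e at 0.27 (SE 0.229). Mature erythrocyte and stromal markers had a median of 0.10 and a mean of 0.08 over 16, also opposite to the test (camera adjusted p = 0.628), with Hba-a2, an alpha globin, at -0.48 (SE 0.225). Above the 95th percentile on every array were 2 of 20 mast cell, basophil and eosinophil markers, Prg2 (8046 in low-ROS CMP) and Epx (3701). So were 4 of 16 erythrocyte and stromal markers, Hbb-b2 (8449), Slc4a1 (6109), Bpgm (3440) and Alas2 (1932). Slc4a1 and Alas2 are also on the erythroid list. Whether RNA of later red cells or eosinophils was in the samples was not tested. No member of the neutrophil, lymphocyte and erythrocyte lists passed over all genes or adjusted over the list alone (0 of 16, 0 of 21 and 0 of 16).

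**Figure D3:**
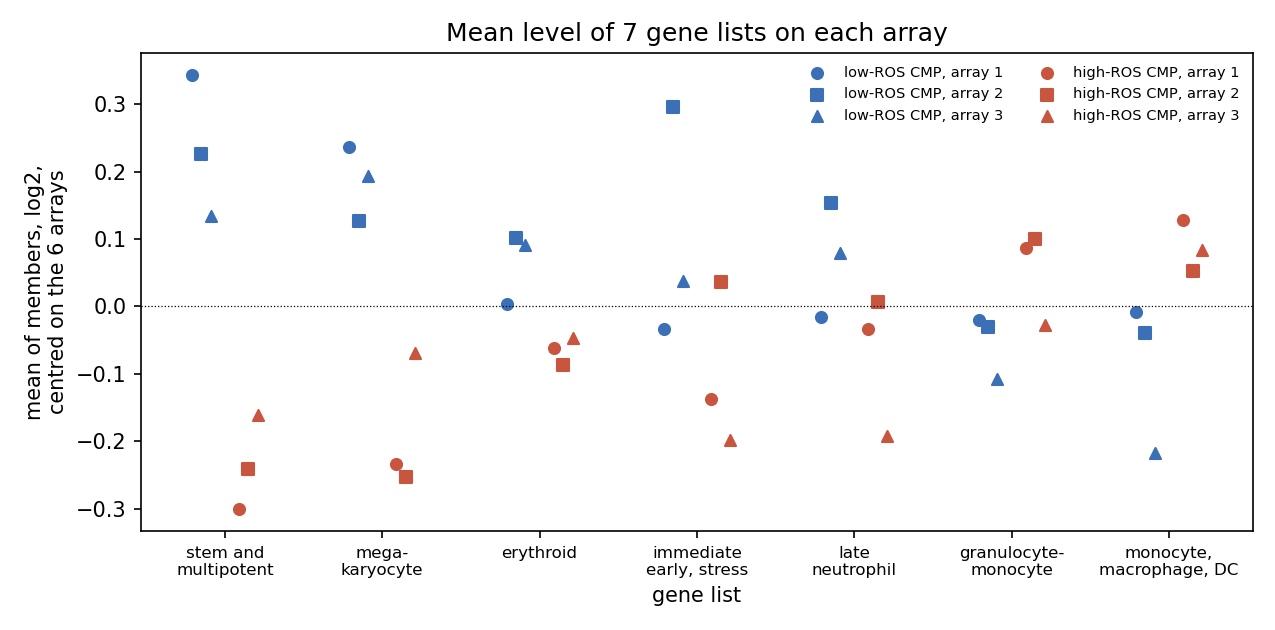
Mean log2 value of the measured members of 7 gene lists on each array, centred on the 6 arrays (vertical axis), for low-ROS (blue) and high-ROS (red) CMP, with a symbol for each replicate number. The low-ROS arrays lie above all high-ROS arrays for the stem and multipotent progenitor list (0.13 or more against -0.16 or less), the megakaryocyte list (0.13 or more against -0.07 or less) and the erythroid list, while the arrays of both groups overlap for the immediate early and late neutrophil lists.

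Of the 21 lists, 8 passed with camera, 6 lower and 2 higher in high-ROS CMP. With an estimated correlation 2 held, the stem and multipotent progenitor list and the megakaryocyte list. The same lists held with fry, which tests whether the genes of a list move one way on balance. The lost calls do not all reflect correlated members. For the erythroid list the estimated correlation was -0.00381, below the preset 0.01, and the unadjusted camera p still rose from 4.80e-05 to 0.00964. That test has fewer degrees of freedom.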

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

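The tests of explanations and of other splits of the arrays in this part were chosen after the results were seen.

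Probe sets that the gene-level comparison does not use also separated the groups. When each of 45037 probe sets was tested alone, 10 passed, of which 3 have no gene name here or several. Probe set 1420444_at, unnamed here, had a log2 fold change of -1.67 (SE 0.131), with 1249 ± 114 (SD, n = 3) in low-ROS and 382 ± 33.5 in high-ROS CMP. Probe set 1416811_s_at is listed for 2 genes, both among the 10 already called, so it repeats that result; it had -1.79 (SE 0.142), with 2183 ± 303 and 619 ± 81.5. Probe set 1440322_at, unnamed here, had 1.17 (SE 0.149), from 1.31 ± 0.218 to 23.2 ± 4.78, all below the median signal of the arrays.

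With 3 arrays against 3 there are 10 splits, so no count of splits can give a share under 0.05. The real split, 1 of 10, had 3 genes higher and 7 lower, and the highest count in either direction in the others was 0. It called 8 lists, and the other splits called 7, 7, 6, 5, 3, 2, 2, 1 and 0, so the number of lists called set the real split little apart. The unadjusted camera p of the stem and multipotent progenitor list was 2.57e-14 in the real split and at the lowest 0.000184 in the others, and that of the megakaryocyte list 4.89e-12 against 3.07e-05; in each case 1 split, the real one, gave a value as small.

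The lower level of stem and megakaryocyte genes in high-ROS CMP was weighed against cells or RNA that could have differed between the sorts. Endothelial cells, which also make Tek, Tie1 and Esam, cannot be told apart from the progenitors as a source, because the 15 endothelial markers, 3 of them on other lists, were mostly near background (median signal 23.9 in low-ROS CMP); their median log2 fold change was 0.12 (SE of the median 0.128), with 9 higher and 6 lower, Kdr (-0.79) and Mmrn2 (-0.65) the furthest, and the highest signals were those of Aqp1, at 679 and 558 in low- and high-ROS CMP, Fabp4, at 259 and 336, Egfl7, at 154 and 210, and Pecam1, at 168 and 192. Platelets or mature megakaryocytes in the low-ROS sort were expected to put abundant platelet transcripts above the median signal there, and clearly lower in high-ROS CMP. Neither was seen for the median of 6 such transcripts (Ppbp, Tubb1, Gp9, Gp1bb, Gp5 and Gp6). Their median signal was 21.4 in low-ROS CMP, near background, and their median log2 fold change -0.0479. Of the 6, Gp9 was above the median signal of the arrays, at 79.4 in low-ROS and 70.5 in high-ROS CMP (log2 fold change -0.19, SE 0.275). Such cells cannot be told apart either, because how these dim probe sets respond was not tested. RNA quality as read by the Gapdh ratio is argued against as the whole cause. With that ratio as a covariate the stem list's median was -0.36, as before, and the megakaryocyte list's -0.29, against -0.26. The larger adjusted p of both lists was 1.56e-10 (1.61e-14 to 0.0271 over all alternatives). This camera test used the preset correlation, and the covariate was not tried with an estimated one or with fry. RNA quality that the Gapdh ratio does not capture was not tested. With the covariate 7 of the 10 gene calls ended, all with larger standard errors, as for Angpt1 (-1.11, SE 0.117, to -1.09, SE 0.143). Rgs1 had a smaller fold as well (-0.73, SE 0.104, to -0.62, SE 0.117). Stem cells within the low-ROS sort cannot be told apart from a different state of the progenitors, because 3 of 27 stem cell genes were higher, none at an unadjusted p under 0.05, and a difference tied to ROS content itself remains open and untested.

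The lower level of immediate early genes may reflect handling or RNA quality of single samples, which were not separated. Of the 9 other splits of the arrays, 1 gave a camera p as small (2.42e-08, against 1.65e-07 for the real one). It set low-ROS replicate 1 with high-ROS replicates 1 and 3, the 3 arrays with the highest Gapdh ratio (3.19, 3.57 and 4.53, against 2.54 to 2.997). That split also had 1585 genes at an unadjusted p under 0.05, more than the 1421 of the real split. The second principal component, with 25.3% of the variance, also set these 3 arrays (-0.228 to 28.7) apart from the others (-15.4 to -12.1). The Actb ratio and the first component did not follow the Gapdh ratio. The Actb ratio was lowest, at 0.976, in low-ROS replicate 1. Low-ROS replicate 1 and high-ROS replicate 3 lay at opposite ends of the first principal component (-25.8 and 36.6). The arrays thus held a structure that matches the split by the Gapdh ratio, but whether RNA quality caused it was not tested. With the Gapdh ratio as a covariate the median log2 fold change shrank from -0.28 to -0.05 (adjusted p = 0.0461). A difference tied to ROS content remains open, and the call was lost with an estimated correlation (adjusted p = 0.326, with 8.85e-09 to 0.341 over all alternatives).

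The high signal of late neutrophil markers on all arrays is consistent with RNA of later neutrophil stages in every sample, since 9 of 16 markers lay above the 95th percentile of genes on every array. The highest signals, which do not rank transcripts by amount, were those of S100a9, S100a8, Chil3 and Ngp, at 12944, 12746, 8271 and 7613 in low-ROS CMP. Saturation or background of these probe sets was not tested, and the highest signals of the arrays were 15128 to 15899. Granulocyte-committed progenitors also make some of these transcripts, among them Fcnb and Chil3, so neutrophil RNA and expression by the sorted progenitors were not separated. A sort on lineage markers would remove neutrophils, and the labels name no such markers.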

How the results depend on the processing

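The stem and multipotent progenitor list and the megakaryocyte list stayed lower and past the threshold in all 19 alternatives, with adjusted p from 1.61e-14 to 0.0271 in each, and the 10 called genes kept their sign in all 16 that refit genes. Of 381 list values under alternatives, 331 stayed on the same side of the threshold. The alternatives without both outlying arrays, with the Gapdh covariate and with unshared members were chosen after seeing the data. Where genes or arrays were left out, fewer were tested; otherwise the cause was not tested. Signal over background limits dim genes such as Slamf1 and Fgd5, with log2 fold changes of -2.00 and -2.19 at pseudocount 1 and -0.55 and -0.32 at pseudocount 64.

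Against 3 genes higher and 7 lower, the counts were 0 and 0 without the mean-variance trend, 5 and 12 among genes above the median signal, 13 and 17 with array weights, 5 and 10 with pseudocount 1, 0 and 4 with pseudocount 64, 0 and 4 without both outlying arrays, 0 and 3 with the Gapdh covariate, 2 and 7 with the mean of probe sets, 1 and 9 probe sets, and 7 and 10 at an adjusted p under 0.1. With the mean of probe sets 6 of the 10 genes passed, and Amot, Cavin2, Cnn3 and Rgs1 did not (log2 fold changes 0.36, -0.63, 0.76 and -0.73). Leaving out each replicate gave 0 higher throughout and 1 to 6 lower. Where limma called 0 genes higher, 549 to 950 were higher at an unadjusted p under 0.05, and without the trend 522 were lower.

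Lists lost their call as follows, in adjusted p. With an estimated correlation, the erythroid list had 0.0675, oxidative phosphorylation 0.515, and FoxO targets, immediate early, late neutrophil and monocyte lists 0.326. With fry the erythroid list had 0.0801, oxidative phosphorylation 0.391, FoxO targets and immediate early genes 0.341, and late neutrophil and monocyte lists 0.313. Oxidative phosphorylation had 0.139 without the trend, 0.0826 above the median signal, 0.0513 with array weights and 0.0505 with pseudocount 1. FoxO targets had 0.0615 without the trend, 0.108 above the median signal and 0.0932 with quantile normalization. With the Gapdh covariate the late neutrophil list had 0.376 and the monocyte list 0.165. The same covariate made other called lists larger, with medians of 0.14 for oxidative phosphorylation (4.70e-07), against 0.05, and -0.13 for FoxO targets (0.00102), against -0.07; quantile normalization gave oxidative phosphorylation 0.10 (0.000710).

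Lists that gained a call were, with quantile normalization, granulocyte-monocyte (0.00369) and ribosome biogenesis (0.0337); with array weights the same lists (0.0173 and 0.0347); without both outlying arrays these (0.00171 and 0.000319), Nrf2 targets (0.0231) and B, T and NK cell markers (0.0308). With the Gapdh covariate they were granulocyte-monocyte (0.00363), ribosome biogenesis (0.000578) and proliferation (1.60e-05), with pseudocount 64 NADPH oxidase (0.049999), and with the mean of probe sets mast cell, basophil and eosinophil markers (0.0437) and the gate's surface proteins (0.0380).

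Leaving out each replicate in turn, adjusted p ranged from 0.00161 to 0.273 for granulocyte-monocyte, 0.0396 to 0.147 for NADPH oxidase, 0.000104 to 0.551 for oxidative phosphorylation, 0.0433 to 0.532 for glycolysis, 0.00356 to 0.228 for FoxO targets, 0.00249 to 0.960 for proliferation, 0.000441 to 0.794 for ribosome biogenesis, 0.0208 to 0.495 for interferon response and 0.000919 to 0.0591 for monocyte markers.

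The labels do not say whether the replicate numbers pair the samples, and the values do not settle it. Deviations from the group means of same-numbered arrays correlated at 0.119, 0.0966 and 0.00275 for numbers 1 to 3. The highest correlation of the same low-ROS arrays with a high-ROS array of another number was 0.0131, -0.0187 and 0.0606. With the replicate number as a block, limma called 0 genes higher and 4 lower (850 and 763 at an unadjusted p under 0.05), all 4 among the 10, NADPH oxidase passed (0.0497) and oxidative phosphorylation did not (0.0501). The block changed no other list call.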

Other observations

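Just short of the threshold, at an adjusted p between 0.05 and 0.1, further genes with groups that did not overlap extend both sides. Besides Tek, those lower in high-ROS CMP were Gnb4, a G protein beta subunit, at 242 ± 19.8 (SD, n = 3) in low-ROS and 92.0 ± 20.4 in high-ROS CMP (log2 fold change -1.27, SE 0.198), and Kcnj5, an inwardly rectifying potassium channel that G protein beta-gamma subunits open, at 120 ± 5.13 and 40.9 ± 5.63 (-1.26, SE 0.201). Those higher were Cacna1d, a voltage-gated calcium channel subunit, at 219 ± 12.6 and 447 ± 41.5 (0.97, SE 0.149), and Fcsk, a fucose kinase, at 51.4 ± 20.4 and 170 ± 4.62 (1.503, SE 0.240), with Tctex1d1 and Bnipl from signals near background. Their adjusted p lay between 0.0623 and 0.0643, and they were chosen after their values were seen.

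Other probe sets did not always move with the chosen one of a named gene. Of 67, each tested alone, 53 had the same sign as the chosen one and 14, of 11 genes, the opposite sign; the genes given here were picked after their values were seen. The other probe sets of Gata2 (log2 fold change -1.48, SE 0.160, adjusted p = 0.0147), F2r (-1.82, SE 0.202, adjusted p = 0.0159) and Angpt1 (-1.54, SE 0.194, adjusted p = 0.0406) passed. Those of Tgfbr3 (-1.76, SE 0.268), Slc14a1 (-0.89, SE 0.178), Cdkn1a (-0.95, SE 0.173) and Kit (-0.82, SE 0.275) had larger folds than the chosen ones and did not pass, nor did those of Slamf1 (-1.66, SE 0.273, and -0.70, SE 0.183).

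For some other genes the value given in the report rests on a single probe set. Ms4a6c had 0.04 on its other probe set against 0.73 on the chosen one, Fbxo32 0.12 and 0.13 against -0.78, Hk1 0.05 against -0.73, Pfkp 0.07 and 0.33 against -0.42, and Dkc1 -0.04 and -0.01 against 0.40. For Irf8 the values were 0.25 against 0.67. The other 6 probe sets of Bcl11a had log2 fold changes from -0.20 to 0.28, against -0.60.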
